A study of Mus musculus with 2 samples.

How the data were processed

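RNA of 2 male C57BL/6 mice labelled cerebellum, 1 control and 1 fed cuprizone, was hybridised to the Affymetrix Mouse Gene 2.0 ST array, per the labels and the series text, which speaks of 2 subjects and does not mention pooling. The authors deposited log2 expression values per probe set, made with RMA in Affymetrix Power Tools per the submitters' processing notes, which give no version. RMA subtracts background, equalises the distribution of probe signals across arrays and summarises the probes of each probe set, so a shift of total RNA between the samples would be removed from the values. The genome build and annotation release are not given in the sources used here. Log2 values were deposited in a pair of tables that held the same 41345 probe sets and differed by at most 5e-05. Medians were 4.33 on the control array and 4.36 on the cuprizone array, quartiles were 3.11 and 5.56 against 3.13 and 5.54, and Pearson's r across probe sets was 0.979, where probe sets are not independent replicates.

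Gene symbols were taken from the annotation columns of the deposited table. A symbol was given for 31873 probe sets and none for 9472, most of which are control or normalization probe sets; 1 probe set that listed a symbol more than once was left out. These gave 30920 genes, of which 657 had over 1 probe set; for those the probe set with the highest mean over both arrays was used. Of the genes, 25452 had a gene ID in a RefSeq gene table for assembly GRCm38.p6, and 1292 of these have another current symbol there; the array's symbols are printed. A gene was counted as measured when the higher of its values reached 4.34, the median of all values, which left 16559 genes. The upper end of the central 95% of 1420 olfactory and vomeronasal receptor genes on each array served as a background bound; this use was added after the data were seen. Differences are cuprizone minus control on the log2 scale with no further centring, with a median of -0.01 over measured genes and a central 95% from -0.49 to 0.50.

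With 1 array per group no test, p-value, SE or SD between samples was computed. Genes were counted when at least 2-fold higher or lower. For each of 32 gene lists and 7 symbol families fixed before the data were examined, the median difference of the measured members was placed among the medians of 10000 random lists of the same size, drawn from measured genes matched in 20 bins of mean expression. A percentile under 2.5 or over 97.5 was called a shift, as a description of these arrays. Shifts were also planted in random genes after shuffling the differences of the 16559 genes for cuprizone against control. A log2 shift of 0.2 was called in 86.5% of 200 simulated lists of 15 genes and 95.0% of lists of 25. Of lists of 15 with no shift, 3.0% were called higher and 2.5% lower. Genes of a real list can vary together, which shuffled random genes do not, so these rates do not carry over to the lists.

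Of the lists, 19 covered myelin and mature oligodendrocytes, oligodendrocyte lineage, cholesterol synthesis, homeostatic and activated microglia, complement and Fc receptors, reactive astrocytes, astrocytes and Bergmann glia, Purkinje cells, granule cells, cerebellar interneurons, integrated stress response, endoplasmic reticulum chaperones, interferon response, antigen presentation, cytokines, copper handling, complex IV and the NRF2 response. The other 13 covered immediate early, glucocorticoid responsive, clock, cell cycle, endothelial, fibroblast, choroid plexus, forebrain, hindbrain, erythroid, leukocyte, male-specific and housekeeping genes. Families were ribosomal protein, olfactory and vomeronasal receptor, keratin and defensin, small nucleolar RNA, microRNA, immunoglobulin segment and predicted Gm genes. A list of dopamine neuron genes was added after values had been seen, as was a list of cerebellum-restricted genes that is not used here, since it was drawn up knowing their levels.

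Named genes followed a rule set beforehand: the 12 largest differences in each direction, leaving out symbol families other than ribosomal and clone names; the 3 members of each of the 19 lists and the 2 members of each of the 13 lists with the largest absolute difference; and Mbp, Mog, Mag, Cnp, Pdgfra, Olig2, Gfap, Aif1, Cd68, Trem2, Gabra6, Pcp2 and Calb1 whatever their values. A gene that repeated a point was left out, and some genes that the rule or the lists name are not reported here. P2ry12, Tmem119, Xist, Drd2, Rgs9 and the dopamine neuron genes were named after their values were seen.

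Alternatives tried were centring on the array median, removal of the level-dependent trend by lowess (span 0.2), quantile normalization, the other deposited table, the mean of a gene's probe sets, no level filter, a filter at the 75th percentile (5.55), a 1.5-fold threshold, counting of all probe sets, list means and unmatched random lists. Added after seeing the data were scaling on hybridization spike-ins, scaling on poly-A spike-ins and leaving out the 5409 cross-hybridising probe sets. Scripts used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, statsmodels 0.14.6 and matplotlib 3.10.9.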

Results

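Gene expression was compared between a control mouse and a mouse fed cuprizone, a copper chelator that kills oligodendrocytes and is used to model demyelination. The labels describe male C57BL/6 mice, a diet holding 0.2% cuprizone for 6 weeks, and cerebellum as the tissue. The sentence about the diet is attached to both samples, so the groups rest on the treatment label of each. The title of the cuprizone sample holds the tag CPZ-5, whose meaning the labels do not give, so the 6 weeks rest on the diet sentence alone. Each group had 1 array, a whole-transcript mouse gene array read as log2 RMA expression for 41345 probe sets. There were no replicates, so no difference below has an error or a test, and each describes these arrays and not the diet in general. The number of arrays limits the precision of every value.

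Gabra6 and Pcp2, set beforehand as checks of the cerebellum label, were at background on both arrays, whereas most genes of the forebrain list lay above it. Gabra6, the GABA receptor subunit of cerebellar granule cells, had a level of 1.84 on the control array and 1.97 on the cuprizone array. Pcp2, a Purkinje cell gene, was at 3.18 and 3.69. Olfactory and vomeronasal receptor genes, which brain tissue barely transcribes, had a central 95% that ended at 4.68 on the control array and 4.71 on the cuprizone array, so both genes lay within that background. The Purkinje and granule cell lists fixed beforehand, which also hold genes that forebrain neurons express, had 15 of 23 and 15 of 22 genes over that bound on both arrays, and the forebrain list, also fixed beforehand, had 17 of 20. Among the latter were the striatal genes Drd2 (6.55 and 6.35) and Rgs9 (7.67 and 7.73). The samples are therefore called the arrays labelled cerebellum, and lists of cerebellar neurons are read with this in mind. The sex label was checked too: Xist was at 2.62 and 2.88, within the receptor background, and the Y-linked gene Eif2s3y was at 6.39 and 6.94.

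**Figure D1:**
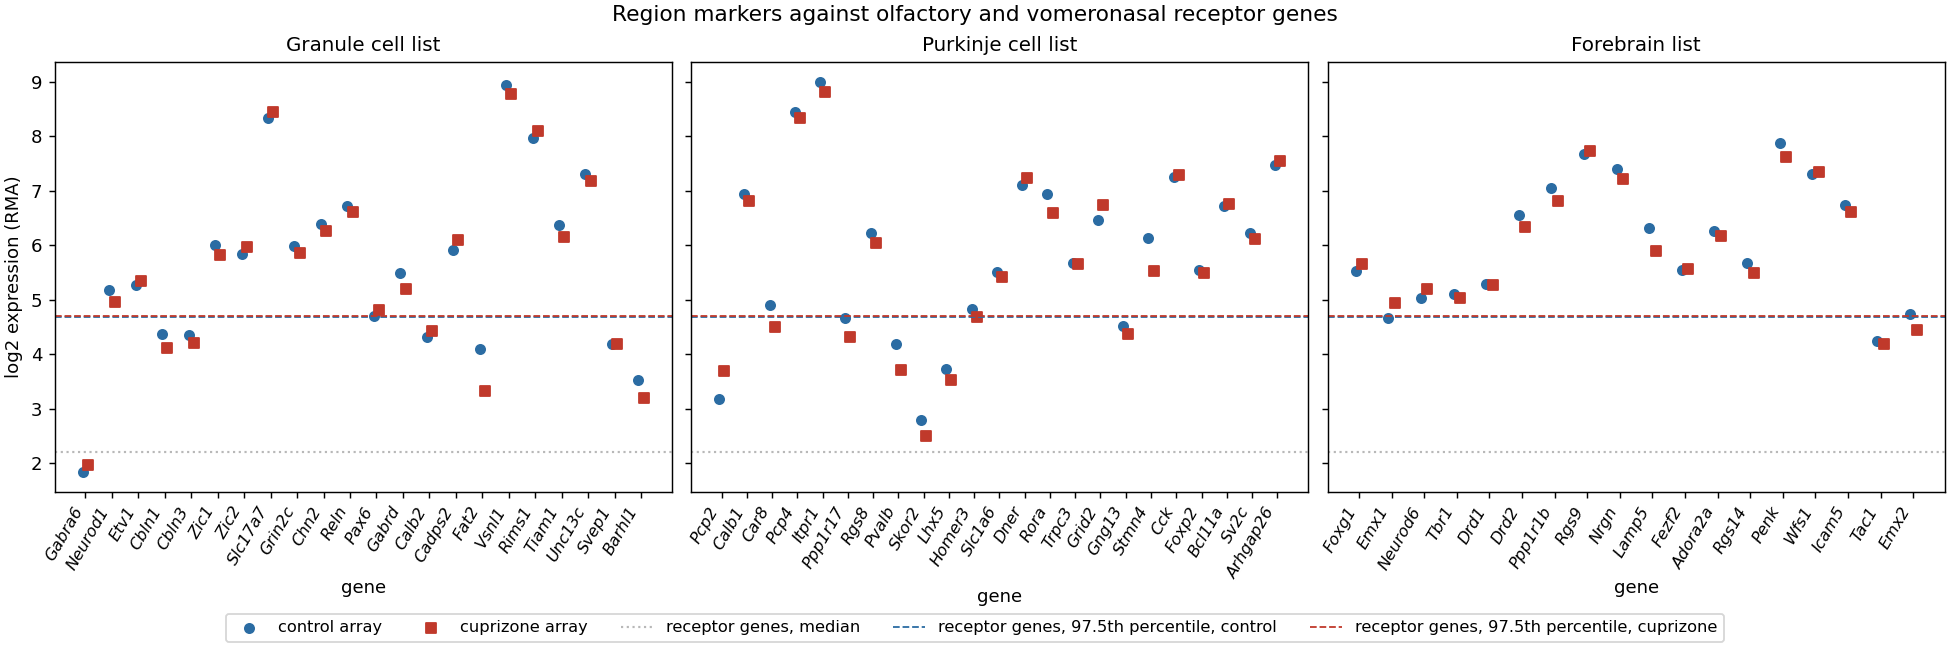
Log2 expression of 22 granule cell genes (left), 23 Purkinje cell genes (middle) and 18 of the 20 forebrain genes (right) on the control array (circles) and the cuprizone array (squares); dashed lines give the upper end of the central 95% of 1420 olfactory and vomeronasal receptor genes per array and the dotted line their median, averaged over the arrays. Gabra6 and Pcp2, first in their panels, lie under the dashed lines on both arrays; above them on both lie 15 genes on the left, 15 in the middle and 15 on the right.

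Myelin genes were among the largest negative differences between the arrays labelled cerebellum, and genes of reactive glia among the largest positive ones. Of 16559 measured genes, 37 were at least 2-fold higher and 21 at least 2-fold lower on the cuprizone array. Members of the microglia, complement and reactive astrocyte lists made up 13 of the higher genes and members of the myelin list 9 of the lower ones, while 20 and 12 were in none of the 19 lists fixed for this tissue and treatment. By level, 19 and 7 had their dimmer value within the receptor background and 5 and 4 had both values there; for named genes with a dimmer value in the background, a fold or difference is given as a lower bound, written "at least", with that value replaced by the upper end of the background on its array. Serpina3n, a protease inhibitor made by reactive astrocytes, had the largest positive difference: its log2 level was 5.20 on the control array and 8.26 on the cuprizone array, which is 8.31-fold. Cd68, a lysosomal protein of phagocytes, was 2.93-fold higher and C4b, a complement component, 2.80-fold. A2m, a broad protease inhibitor, was at least 2.92-fold higher, the myeloid inhibitory receptor Lilrb4a at least 2.24-fold and Gpnmb, a glycoprotein of phagocytes, at least 2.01-fold. Mobp, a structural protein of central myelin, had the largest negative difference among genes with a single probe set, with 9.24 on the control array and 7.32 on the cuprizone array, a 3.80-fold difference. Mal and Anln, both expressed by myelinating oligodendrocytes, were 2.82-fold and at least 1.53-fold lower. S1pr5, the sphingosine-1-phosphate receptor of oligodendrocytes, was at least 1.88-fold lower, and Lmod1, a smooth muscle actin nucleator, at least 1.01-fold. The array annotation places Serpina3n on chromosome 12 from 104406708 to 104414329 and Mobp on chromosome 9 from 120149742 to 120176091; the genome build is not given in the sources used here.

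Some of the largest values rest on weaker probe sets. The largest negative difference of all, for Kctd13, came from a short probe set on chromosome 7 from 126947561 to 126947661 that the annotation marks as cross-hybridising, with a log2 difference of -2.41. Its other probe sets were lower by at least 0.85 and by 0.23. For Mid1, a cross-hybridising probe set on chromosome Y gave -1.74, and the probe set on chromosome X was lower by at least 0.25. Among the 12 largest positive differences, n-R5s8, a 5S ribosomal RNA locus, was at 3.68, within the background, and 5.17. Cross-hybridising probe sets supplied 5 of the 37 higher genes and 5 of the 21 lower genes. Predicted genes named only by a Gm number made up 6 of the higher and 4 of the lower genes.

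**Figure D2:**
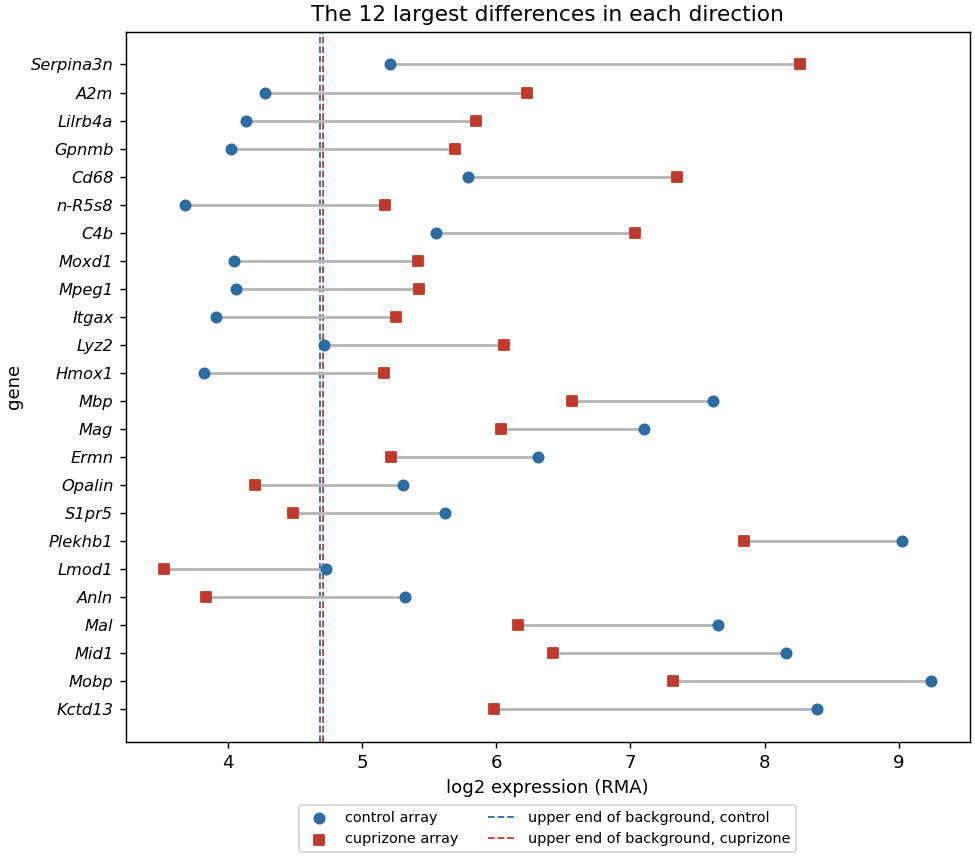
Log2 RMA expression on the control array (circles) and the cuprizone array (squares) for the 12 named genes with the largest positive difference and the 12 with the largest negative difference; a grey line joins the values of a gene, and dashed lines mark the upper end of the receptor background, 4.68 and 4.71. Serpina3n runs from 5.20 to 8.26 and Mobp from 9.24 down to 7.32.

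Myelin genes were lower on the cuprizone array as a group. The list of myelin and mature oligodendrocyte genes had 43 measured members, of which 37 were lower, 20 at least 1.5-fold lower, 9 at least 2-fold lower and 0 at least 1.5-fold higher; with values in the background raised to its upper end, 7 were at least 2-fold lower. Its median log2 difference was -0.55, below all 10000 random lists of the same size and expression level. Mbp, the basic protein that compacts myelin, went from 7.61 on the control array to 6.56 on the cuprizone array, a log2 difference of -1.05. Mag, an adhesion molecule of the inner myelin wrap, differed by -1.07, and Mog, a surface protein of the outer wrap, by -0.91. Cnp, an enzyme of myelin's cytoplasmic channels, differed by -0.64. Ermn, a marker of mature oligodendrocytes, differed by -1.10, and Opalin, another, was at least 1.51-fold lower.

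Genes of the oligodendrocyte lineage and its precursors did not share this difference. Their median over 20 measured members was 0.05, at percentile 89.51 of the random lists, and 0 members differed by 1.5-fold. Pdgfra, the growth factor receptor of precursor cells, differed by 0.10 and Olig2, a transcription factor of the whole lineage, by 0.01. The largest values in the list were 0.36 for Sox6, -0.34 for Sox8 and 0.33 for Tcf7l2. Cholesterol synthesis, on which myelin membrane depends, was lower: the median of 26 measured genes was -0.32, below all random lists, with 22 members lower and 3 higher. Hmgcs1, an early enzyme of the pathway, differed by -0.74, Insig1, its sterol-regulated brake, by -0.69, and Cyp51, a late demethylase, by -0.61. The myelin and cholesterol lists kept their sign and stayed below the central 95% of random lists under all 12 alternatives. Calls kept under median centring, spike-in scaling and the other deposited table were nearly fixed in advance. These leave a list's place among random lists nearly unchanged.

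Neuronal lists lay toward the lower end of random lists, with smaller medians than the myelin list. Medians were -0.11 for Purkinje cell genes (percentile 3.76), -0.14 for granule cell genes (2.55), -0.13 for cerebellar interneuron genes (4.22) and -0.13 for forebrain genes (2.93), all inside the central 95% of random lists but near its lower end. Some alternatives put them outside it: granule cell genes with the mean of probe sets (percentile 1.99), no level filter (1.18) and unmatched random lists (2.36), Purkinje cell genes with no level filter (1.27) and the list mean (1.89), and forebrain genes with the 75th percentile filter (1.23). Others moved them inward, and with the list mean granule cell genes had -0.06 at percentile 20.49. Calb1, a calcium buffer of Purkinje and many forebrain neurons, differed by -0.11. Larger values were those of Stmn4 (-0.60), Lgi2 (-0.38), Rora (-0.36), Gad1 (-0.30), Gabrd (-0.29) and Lamp5 (-0.41). The hindbrain and brainstem list had a median of -0.32 at percentile 0.57, with only 6 of 23 genes measured and 3 above the receptor background on both arrays. Nefh, the heavy neurofilament of large axons, differed by -0.52, and Th, the rate-limiting enzyme of dopamine synthesis, was at least 1.23-fold lower. With no filter on low levels this list's median was 0.013, and with hybridization spike-in scaling its percentile was 4.74.

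Genes of activated microglia and complement were higher on the cuprizone array under every scaling, though by less with poly-A spike-in scaling. The list of activated microglia and phagocyte genes had a median of 0.55 over 28 measured members, above all 10000 random lists. A gene counted as measured by the higher of its values, so members could enter through the cuprizone array alone. With no level filter the median was 0.52 over 35 members. With poly-A scaling the median was 0.13, and random lists move down with it, so its place among them is no further check. Of the 28 measured members, 26 were higher, 12 by at least 1.5-fold and 7 by at least 2-fold. With values in the background raised to its upper end, the latter counts were 10 and 5. Cd68 went from 5.79 to 7.34, a difference of 1.55. Lyz2, the lysozyme of myeloid cells, differed by 1.34; the myeloid genes Itgax and Mpeg1, within the background on the control array, differed by at least 0.57 and at least 0.74. Trem2, the lipid receptor of microglia, differed by 0.71. Complement and Fc receptor genes had a median of 0.64 over 12 measured members, above all random lists, with 11 members higher. With no level filter the median was 0.51 over 18 members. With poly-A scaling the median was 0.23. C4b differed by 1.48 and Fcgr2b, an inhibitory antibody receptor, by at least 0.80. C1qc, a chain of the initiating complex, went from 5.03 to 6.03.

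Homeostatic microglia genes had a median of 0.32 over 19 measured members, above all random lists, which turned to -0.12 with the arrays scaled on poly-A spike-ins. Within this list 14 members were higher and 5 lower. The sialic acid receptor Cd33 differed by 0.91, the Fc receptor-like gene Fcrls by 0.85 and Ptprc, the pan-leukocyte phosphatase, by at least 0.34. P2ry12, a surface marker of resting microglia, differed by 0.11. Tmem119, another, was at 4.82 and 4.66, and Aif1, a cytoskeletal marker of all microglia, at 4.49 and 4.74, so each lay within the background on 1 array. Infiltrating leukocyte genes had a median of 0.00 over 5 measured members of 20, of which 4, Cd4 and Nkg7 among them, lay within the background on both arrays. With no level filter the median of this list was 0.22, at percentile 99.18. Genes for cytokines and chemokines had a median of -0.02 over 10 measured members, at percentile 44.98, but -0.42 over the 3 members left by the 75th percentile filter, at percentile 0.06. Among them Ccl3 differed by at least 0.82, Il33 by -0.44 and Cxcl12 by -0.42.

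Genes of reactive astrocytes stood above matched random lists, whereas general astrocyte genes did not. The reactive astrocyte list had a median of 0.37 over 17 measured members, above all random lists. A gene counted as measured by the higher of its values, so members could enter through the cuprizone array alone. With no level filter the median was 0.33 over 31 members, also above all random lists. The median turned to -0.26 with poly-A spike-in scaling and was 1.17 over the 4 members left by the 75th percentile filter. That filter takes the higher of a gene's values. Serpina3n (5.20 on the control array) and Osmr (4.93) passed it only through the cuprizone array. Of the measured members, 16 were higher and 3 at least 2-fold higher. After Serpina3n, the largest differences were those of Gfap, the intermediate filament of astrocytes (a difference of 1.17), and Osmr, the oncostatin M receptor (1.17). The list of astrocyte and Bergmann glia genes had a median of -0.03 over 22 members, at percentile 45.84 of random lists, with -0.55 for the amino acid transporter Slc7a10, -0.43 for the growth factor receptor Fgfr3 and -0.38 for the acyl-CoA synthetase Acsbg1.

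**Figure D3:**
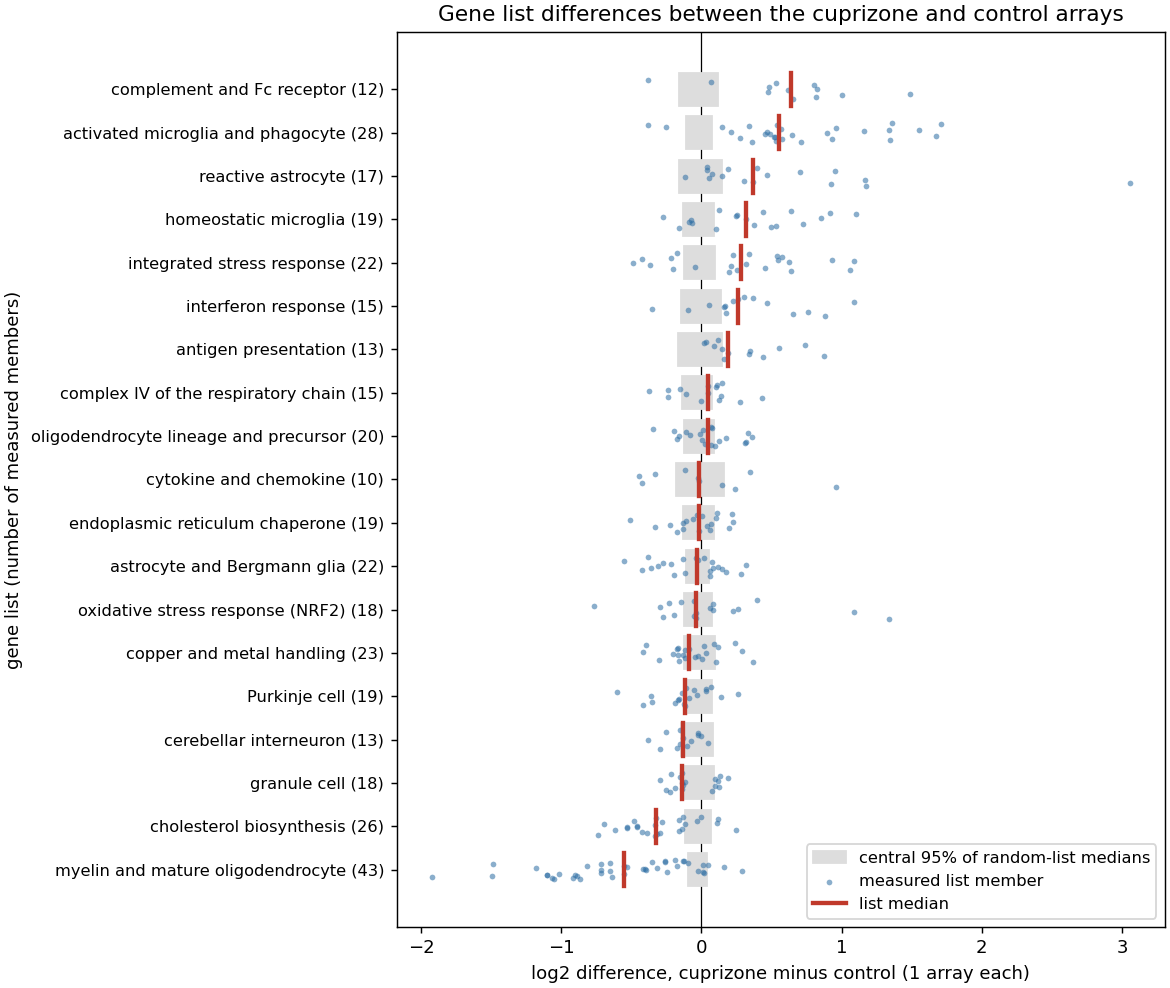
Log2 difference (cuprizone minus control, 1 array each) of every measured member (points) and the median (red line) of 19 gene lists; grey boxes span the central 95% of medians of 10000 random lists matched on size and expression level. Medians run from -0.55 for myelin genes to 0.64 for complement and Fc receptor genes; with poly-A spike-in scaling, of the lists with positive medians only activated microglia and complement stay positive.

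Stress and immune response lists also stood above matched random lists. Integrated stress response genes had a median of 0.29 over 22 measured members, above all random lists, with 15 higher and 7 lower. Both values lay within the background for 4 of them. The median was 0.24 over 26 members with no level filter, -0.18 with poly-A scaling and 0.44 over 10 members with the 75th percentile filter. Slc7a11, the cystine importer, differed by 1.09, the transcription factor Atf5 by 1.06 and Slc7a5, a large amino acid transporter, by 0.93. Interferon response genes had a median of 0.26 over 15 members (percentile 99.96). It was 0.215 over 26 members with no level filter, -0.16 with poly-A scaling and 0.55 over 4 members with the 75th percentile filter. That filter takes the higher of a gene's values, and Ifit1 (4.90 on the control array) passed it only through the cuprizone array. Values were 1.09 for Lgals3bp, 0.88 for Ifit1 and at least 0.42 for Oasl2. Antigen presentation genes had a median of 0.19 over 13 members (percentile 99.24), against -0.0701 and -0.22 with hybridization and poly-A spike-in scaling and 0.34 over 5 members with that filter. All 13 were higher as deposited, with 0.87 for B2m, the shared light chain of class I molecules, and 0.74 and at least 0.47 for the class II genes Cd74 and H2-Ab1.

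The pathways closest to the chemistry of cuprizone showed no shift of their list medians. Copper and metal handling genes had a median of -0.09 over 23 members (percentile 8.62), with -0.39 for the ferroxidase Heph and 0.37 for the metallothionein Mt2. Complex IV, the copper enzyme of the respiratory chain, had a median of 0.05 over 15 members (percentile 92.87), with 0.43 for Cox6b1, -0.38 for Cox10 and 0.28 for Cox4i1. Endoplasmic reticulum chaperones had a median of -0.02 over 19 members (percentile 47.48), with values of -0.33 for Dnajb11 and -0.22 for Calr. The NRF2 list of oxidative stress genes had a median of -0.04 over 18 members (percentile 39.10), with 8 higher and 10 lower. Slc7a11, also a member of this list, differed by 1.09 and the heme oxygenase Hmox1 by at least 0.48, while G6pdx was at least 1.55-fold lower. With the list mean the NRF2 value was 0.08, at the threshold for a higher call but not past it. The place of this list among random lists therefore depends on the statistic used.

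Lists for other cells and for the state of the tissue are given for comparison. Endothelial and mural genes had a median of -0.13 over 21 members (percentile 1.78), with -0.59 for Cldn5 and -0.45 for Cdh5, both junction proteins of vessels; with no level filter its percentile was 2.81, inside the central 95%. Fibroblast and meninges genes had a median of 0.17 over 15 members (percentile 99.82), turning to -0.091 and -0.24 with hybridization and poly-A spike-in scaling, with 0.40 for Fmod and 0.33 for Igf2. Immediate early genes had a median of 0.13 over 21 members (percentile 99.49), turning to -0.15 and -0.30, with at least 0.91 for Cyr61 and at least 0.44 for Npas4. Medians were 0.06 for choroid plexus and ependyma (Ttr 0.43, F5 0.52), 0.087 for erythroid (Hbb-bt at least 0.29, Bpgm -0.42), 0.00 for glucocorticoid responsive (Cdkn1a 1.11, Nfkbia 0.59), 0.01 for circadian clock (Nfil3 -0.35, Cry1 -0.30), -0.02 for cell cycle (Ccna2 and Cdc20 within the background on both arrays) and -0.05 for housekeeping genes (Actb -0.16, Ywhaz -0.15), all within the central 95% of random lists. The Ywhaz value came from a cross-hybridising probe set, and the gene's other probe set differed by -0.02. The 4 measured Y-linked genes had a median of 0.23 (percentile 99.54), turning to -0.023 and -0.17 under the spike-in scalings. Values were 0.55 for Eif2s3y and 0.31 for Uty.

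Scaling on spike-ins lowers every difference by the same amount, 0.26 for hybridization spike-ins and 0.40 for poly-A spike-ins, so the counts past a threshold move by construction. The 37 higher and 21 lower genes became 16 and 92 with the former and 8 and 250 with the latter. Since every difference falls, all 21 lower genes had to stay among the lower ones, which is no further support.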

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

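The tests of each explanation in this part were chosen after the results were seen, and those on blood, scatter and microglial state were redefined after an earlier form had given values. The gene lists, Gabra6 and Pcp2 as label checks, removal of the level-dependent trend and the use of no level filter had been set before the data were examined. Control probe sets stand outside the comparison of genes, and several kinds of them were brighter on the cuprizone array among those above the level minimum. The 24 poly-A spike-ins, RNA added before labelling, had a median log2 difference of 0.40, with 24 of 24 higher. The 14 hybridization spike-ins, added after labelling, had 0.26, and 16 other Affymetrix controls had 0.32. The 2644 intron probe sets of normalization genes had 0.060, with 1438 higher and 1196 lower, against -0.056 for their 1215 exon probe sets. Other kinds were dimmer: 8 antigenomic background probe sets had -0.05 with 8 lower, and 20 ribosomal RNA probe sets had -0.09 with 15 lower.

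The lower myelin list was weighed first. A level-dependent error of scaling is argued against, since the median was -0.53 after the level-dependent trend was removed, against -0.55 before. It remained below all random lists, but these are matched on expression level, so removing the trend could hardly change that place. A cuprizone sample with less hindbrain or white matter tissue stays open: the hindbrain list lay at percentile 0.57, but it had 6 measured members and a median of 0.013 when the genes near background were added, and 19 of its 23 genes exceeded the receptor background on neither array. With 1 array per group, the tissue taken and the diet cannot be told apart. An effect of the diet on oligodendrocytes is untested here and also stays open.

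The higher microglial and reactive astrocyte genes were weighed next. Scatter of dim probe sets is argued against for activated microglia genes. The 11 of them at or above the 75th percentile of levels on the control array had a median of 0.45, above all random lists of genes chosen the same way. Homeostatic microglia and reactive astrocyte genes were not tested this way, so scatter stays open for them. Of 31 reactive astrocyte genes 17 were measured, and 4 of these had both values within the background. Residual blood stays open: the erythroid median of 0.087 lies under the 0.55 of activated microglia genes, but 5 of 6 measured members were higher, Hbb-bt by at least 0.29, and their SD was 0.45. More microglia of the same state would move homeostatic and activated genes alike; the activated median was higher by 0.23, above the central 95% of random divisions of the members between the lists for 3 of 4 choices of members (percentiles 98.11, 98.04 and 97.54) but at 97.39 with all members. More microglia and a shift of microglial state therefore cannot be told apart here, and an effect of the diet stays open and untested.

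The region markers were weighed last. Cerebellum as the main tissue behind the RNA is argued against: Gabra6 and Pcp2, chosen as label checks before the data were examined, reached at most percentile 89.4 of receptor genes on either array. The forebrain list had a median level at percentile 99.9 or more on both, as forebrain RNA on the arrays would give. The cerebellar lists lay nearly as high on the control and cuprizone arrays. They were at 99.9 and 99.8 for Purkinje cells, 99.7 and 99.6 for granule cells and 99.9 and 99.9 for interneurons. List medians against this background therefore cannot separate the regions, and no conclusion is drawn from them. The source name of both samples is brain, so a tissue label that differs from the dissected tissue is a candidate explanation; a small share of cerebellum, and probe sets that do not respond, stay open. No biological explanation was tested for this pattern, since both groups show it.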

How the results depend on the processing

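The spike-in scalings and the set without cross-hybridising probe sets were chosen after seeing the data. Myelin medians ran from -0.96 to -0.53 over 12 alternatives and cholesterol medians from -0.73 to -0.29. Activated microglia medians ran from 0.13 to 0.70 and complement and Fc receptor medians from 0.23 to 0.80. Each list kept its direction and call. Median centring and spike-in scaling move a list and its random lists alike, and the other deposited table holds nearly the same values. Calls kept under these are no further support. The counts of 37 higher and 21 lower genes became 105 and 60 with no level filter, 16 and 11 with the 75th percentile filter, 265 and 223 at 1.5-fold, 182 and 178 over all probe sets, 16 and 92 with hybridization spike-in scaling and 8 and 250 with poly-A spike-in scaling. The filter, threshold and probe set counts moved by construction, since fewer or more features could pass. Most of the 182 and 178 probe sets were normalization controls, with 99 and 104 for introns and 43 and 47 for exons. Probe sets of the array's main category gave 38 and 26, near the gene counts. Poly-A spike-in scaling turned the medians of homeostatic microglia (-0.12), reactive astrocyte (-0.26), integrated stress response (-0.18), interferon response (-0.16), antigen presentation (-0.22), immediate early (-0.30), fibroblast (-0.24) and Y-linked genes (-0.17); hybridization spike-in scaling turned those of antigen presentation (-0.0701), immediate early (-0.15), fibroblast (-0.091) and Y-linked genes (-0.023). These scalings subtract 0.40 or 0.26 from every difference, and the level minimum was applied anew, so measured members could change too. Random lists move by the same amount, so percentiles can change only through the members. That each of these lists stayed above the central 95% of random lists under both scalings is therefore no further support. With the 75th percentile filter the medians were 1.17 for reactive astrocyte (4 members), 0.44 for integrated stress response (10), 0.55 for interferon response (4) and 0.34 for antigen presentation genes (5). That filter takes the higher of a gene's values, so genes can pass through the cuprizone array alone. Serpina3n, Osmr and Ifit1 did so, which can raise these medians. The hindbrain median was 0.013 with no level filter. Granule cell genes lay under percentile 2.5 with the mean of probe sets, no filter and unmatched random lists (-0.14 each), Purkinje cell genes with no filter (-0.12) and with the list mean (-0.12), cytokine genes with the 75th percentile filter (-0.42) and forebrain genes with the 75th percentile filter (-0.16), and leukocyte genes lay above the central 95% with no filter (0.22). Endothelial genes lost their call with no filter (-0.11), hindbrain genes with hybridization spike-in scaling (-0.49) and Y-linked genes, at the threshold, with unmatched random lists; the cause was not tested. Of 840 alternative values of named genes, 671 moved by less than the SD of differences of genes at the same level. Many of these could hardly move. The other deposited table holds nearly the same values, and the mean of probe sets leaves genes with a single probe set as they were. Median centring and spike-in scaling shift every gene alike. The count is therefore no measure of how stable the named genes are. Differences scattered more among dim genes: of 20 level bins, the SD was 0.29 in bin 2 from the dim end and 0.19 in the brightest. The dimmest bin had 0.44, but its mean level of 4.255 lay under the level minimum of 4.34. Genes with a mean under that minimum were kept only if their values differed, so the filter itself raises this SD.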

Other observations

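Terms of the array's own gene annotation were ranked by their median difference. Among 513 biological process terms with 15 to 150 measured genes, the highest median difference was that of classical complement activation (0.36 over 16 genes), followed by response to wounding (0.17 over 21). Amino acid transport had 0.12 over 29 genes, above all 2000 random lists drawn per term. On the lower side, after sterol biosynthesis (-0.31 over 20 genes) came glutamine metabolism (-0.23 over 16), memory (-0.17 over 26) and the tricarboxylic acid cycle (-0.16 over 25). The term myelination had a median of only -0.14 over 32 genes (percentile 0.40), with 2 of them at least 2-fold lower, a far smaller value than that of the fixed myelin list. Over all terms, 19 lay above and 37 below the central 95% of random lists, where 12.8 per side would lie by chance; terms share genes, and they were chosen after the data were seen.

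Genes of dopamine neurons were lower on the cuprizone array. The list, written after some of its values had been seen, had 8 measured members with a median of -0.34, and 7 of them were lower. The dopamine transporter Slc6a3 went from 5.90 to 4.93, a difference of -0.97, beside -0.68 for Aldh1a1, an enzyme of a subset of these neurons. The cell bodies of these neurons lie in the midbrain, and 1 array per group gives no means of separating a difference in dissection from the diet.

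Small RNA loci parted from other genes of their level in opposite directions. The 100 measured small nucleolar RNAs had a median of -0.10, at percentile 0.05 of matched random lists, and the 221 microRNA loci had 0.11, above all random lists. The other families had 0.03 for ribosomal protein genes (percentile 96.64), 0.03 for predicted Gm genes (above all random lists, over 1984 genes), 0.02 for 74 receptor genes, 0.04 for keratin and defensin genes and -0.03 for immunoglobulin segments.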
